A study of Mus musculus with 4 samples.

How the data were processed

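AGO2 eCLIP was carried out on whole brain of C57BL/6 mice at postnatal day 0, wild type and Fmr1 knockout, with the anti-AGO2 antibody EAG009 of the provider to which the brains were sent, eClipse BioInnovations. The labels list 4 samples, an IP and an input per genotype. Processed files belong to the 2 IP samples, and a further table belongs to the series. The inputs enter only through the scores of the IP files.

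Per the submitters' processing notes and the labels' protocols, adapters were trimmed with Cutadapt 1.15, reads on mouse repeats were removed and the rest mapped to mm10 with STAR 2.6.0c, and PCR duplicates were removed with UMI tools, whose version the labels give as 5.2. Clusters were called in each IP with CLIPper 1.4, and their read density was compared with the size-matched input by a custom script. Each deposited file gives, per cluster, the authors' -log10 p, at most 400, and the authors' log2 of read density in the IP over the input, scaled to library totals. In the deposited series table, the -log10 p and log2 set the wild-type IP against the knockout-labelled IP. How that table was made is not stated: 46799 of its 46862 regions are exactly those of the wild-type file, so wild type was taken as the numerator. All scores per region are the authors'; no reads were remapped.

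The build was checked: all 21 chromosomes of the mm10 reference hold their regions, and 44940 of 44973 annotated start codons read ATG. Read counts were recovered from the scores. The log2 values fell on a constant plus the log2 of a ratio of whole numbers (denominator at most 1000) in 99.97% of wild-type, 99.97% of knockout-labelled and 99.96% of series regions. A read count of 0 in the denominator had been counted as 1. The listed -log10 p was met within 1% for all regions with such a ratio and a -log10 p between 0 and 400. It was computed with a 2-sided exact binomial test at the fixed depth ratio. Where observed and expected reads were at least 5, a chi-square test with Yates correction was used. For 42616 regions the wild-type reads found from both tables were equal in 100% of cases, and 46442 series regions had reads of both IPs. Regions with a listed -log10 p of 0 or 400 in every table that holds them gave no reads.

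A cluster counted as an enriched peak at a -log10 p of 3 or more and a log2 of 3 or more. Each region took the annotation at its midpoint on its strand, in the order coding sequence, 3' UTR, 5' UTR, non-coding exon and intron, and regions at miRNA genes were also counted on their own. Overlap meant 1 base or more on the same strand, beside 100 random moves of the peaks within the same kind of region of the same gene. Regions of the series table counted as higher or lower at a -log10 p of 3 or more and a log2 of 1 or more in size. A comparison of the reads of 2 libraries compares those libraries and not the genotypes, and with 1 library per genotype no test across libraries could be made.

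A gene's value was the median log2 of its exonic regions in the series table. The median over each of 18 gene lists was placed among 10000 random lists of the same size, matched on the number of clusters per gene in 20 bins. The lists were FMRP-bound mRNAs; miRNA pathway and silencing complex partners; let-7, miR-124 and miR-9 targets; transcription factors of neuron formation; cytoskeleton and axon guidance; synapse and ion channels; cell cycle; translation and ribosome; and markers of neurons, neural progenitors, astrocytes, oligodendrocyte lineage, microglia, endothelial and mural cells, erythroid cells and choroid plexus.

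Seed sites of each miRNA family were sought in enriched 3' UTR peaks and in 5 same-length windows per peak from the same 3' UTR outside any cluster, with intervals from 1000 resamples of genes. Predicted G-quadruplexes were 4 runs of at least 3 guanines with loops of up to 7 bases on the transcript strand, within 50 bases of enriched exonic peaks, beside 10 draws of windows of the same kind of region and gene. Shares carry exact (Clopper-Pearson) 95% binomial intervals.

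The genes named were Fmr1; the 10 highest and 10 lowest genes of the series table by -log10 p among exonic regions past the limits; the 10 genes with the highest -log10 p in each library; and up to 4 members of each list with the largest log2 in size past the limits, or with the most enriched peaks where none passed. This rule, the lists, the limits, the comparisons and most alternatives were set before the data were examined. Alternatives covered the limits, equal numbers of peaks, the rule for overlap, the order of annotations, centring of log2, matching of lists and the definition of sites and motifs. Added after the data had been seen were ranks among protein-coding genes, sites with no cluster of the other library nearby, examples of sites and motifs, thinning of the wild-type input, p in both directions, merging of abutting peaks, peaks at miRNA genes left out, reads summed per gene, lists matched on reads and extended peaks for seeds. The lowest genes of the series table were ranked by the added p, because none passed by the deposited one. Some genes that these ranks reach are not reported.

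The steps were tested on simulated data. Read recovery was exact in 100% of the simulated regions of each comparison with p between 0 and 400 (20000 simulated each). Those scores were simulated with the same formulas that the recovery inverts. The test therefore checks the inversion and not how the authors' scores were made. In simulated series regions with 20 or more reads, 0.065% of 20000 with a true log2 of 0 were called, 21% of 200 at a log2 of 1, 74% at 2 and 97% at 3, but 10% at -1, 38% at -2 and 53% at -3. Lower regions are therefore found less often than higher ones of the same size. Read totals were drawn from regions with a listed -log10 p between 0 and 400, with binomial error only. The choice of regions in the wild-type IP was not simulated. These rates therefore do not cover regions with fewer reads, among them many of the list members named below. Among 6000 simulated genes, 4% of 200 unshifted lists lay outside the central 95% and 97% of lists shifted by -1 did. For 3000 simulated seed peaks with a true ratio of 3, the mean ratio found was 3.00 and 95.5% of intervals held it. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and bedtools 2.31.1.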

Results

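AGO2, the Argonaute protein that carries miRNAs to their target RNAs, was crosslinked to RNA and immunoprecipitated (eCLIP) from whole brain of C57BL/6 mice at postnatal day 0. The labels name 4 libraries: an AGO2 immunoprecipitate (IP) and an input from wild-type brain, and the same pair from Fmr1 knockout brain. Fmr1 encodes FMRP, the RNA-binding protein that is lost in fragile X syndrome. The files hold 46860 clusters of reads called in the wild-type IP and 86106 called in the IP labelled Fmr1 knockout, each scored against its own input, and a table of 46862 regions that sets the wild-type IP against the other. Library totals are not in the files. The scores themselves fix the depth ratios: the input was 6.34 times as deep as the IP in wild type and 1.92 times in the knockout-labelled pair, and the knockout-labelled IP was 2.28 times as deep as the wild-type IP. The median cluster held 4 IP reads in either library. Each genotype had 1 IP library, so every difference between genotypes below is a difference between 2 libraries with no replicate check. Intervals are exact 95% binomial intervals and cover counting error only.

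Fmr1 RNA gave reads in both pairs of libraries. On Fmr1 (ENSMUSG00000000838.17, mm10 chromosome X, 68678541 to 68717963, plus strand) the wild-type IP had 2 clusters and the IP labelled knockout had 5, all in exons, and none was enriched over input. In wild type, the coding cluster at 68712333 to 68712404 held 5 IP and 14 input reads (log2 over input 1.18), and the 3' UTR cluster at 68716299 to 68716338 held 4 IP reads against 1 input read (4.66). In the other library, the 5' UTR cluster at 68678727 to 68678834 held 11 IP and 6 input reads (1.81). Coding clusters at 68713250 to 68713325 and 68715557 to 68715613 each held 7 IP reads, against 12 and 11 input reads (0.16 and 0.29), and the 3' UTR cluster at 68715697 to 68715751 held 3 against 2 (1.52). The remaining coding cluster, at 68712325 to 68712373, lay below its input (-1.52). In the authors' deposited table, the wild-type regions of Fmr1 had log2 values of 0.93 in the coding sequence (5 wild-type against 6 other reads) and 1.60 in the 3' UTR (4 against 3). The labels do not give the allele, so these reads may lie outside the part that was deleted, and they check neither the genotype nor the label. The library is therefore called the knockout-labelled library.

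RNA of miRNA genes was the most enriched with AGO2 in both libraries. In wild type, the 10 genes ranked highest by the authors' -log10 p (400 each, ties by log2) were all miRNA genes, led by Mir298 (log2 over input 12.98), Mir99a (12.89), Mir300 (12.74), Mirlet7b (12.67), Mirlet7i (12.55) and Mir301 (12.49). Mir125a (12.43), Mir126a (12.40), Mir135a-2 (12.30) and Mir135b (12.22) followed. In the knockout-labelled library, Mir99a (11.30), Mir125a (10.92), Mirlet7i (10.56), Mir149 (10.55) and Mir301 (10.45) ranked highest, then Mir135a-2 (10.45), Mirlet7b (10.43), Mir298 (9.84), Mir300 (9.77) and Mir126a (9.59). Peaks at miRNA genes numbered 583 of the enriched peaks in wild type (5.16%, interval 4.76 to 5.59; median log2 8.81) and 491 in the knockout-labelled library (18.5%, 17.1 to 20.1; median 7.01). Some miRNA genes are cut into abutting regions with the same log2, as Mir128-1 at 128202402 to 128202410 and 128202411 to 128202421 in the deposited comparison of the IPs. Such regions may rest on the same reads, and the intervals treat them as independent.

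Among protein-coding genes, ranked after the data had been seen, Igf2, an imprinted growth factor gene, led both libraries with a 5' UTR peak (log2 over input 11.73 in wild type and 7.61 in the knockout-labelled library). Myadm carried a 3' UTR peak at 8.68 and 6.44, and Kdm6b, a histone H3 lysine demethylase gene, a coding peak at 8.14 and 4.96. The 3' UTR of Ids, which encodes a lysosomal sulfatase, had 7.58 and 7.89. The 3' UTR of Nfix, a nuclear factor I gene, had 5.66 and 6.90. In the 3' UTR of the protocadherin gene Pcdh1, the best-scoring peaks were different ones, 6.48 in wild type and 4.53 in the knockout-labelled library, which do not overlap. Rpl14 (6.94), Prr36 (5.97), Snhg11 (5.10) and Gabbr1, a GABA-B receptor subunit gene (5.03), completed the wild-type ranks. The knockout-labelled ranks also held Kcnk10, a potassium channel gene (8.39), Tsc22d4 (7.77), the transcription factor gene Zfhx3 (6.80) and 2410002F23Rik (5.41).

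At limits of 3 for both -log10 p and log2 over input, 11289 wild-type clusters were enriched peaks (24.1%), against 2651 in the knockout-labelled library (3.08%). Exonic enriched peaks lay on 3306 protein-coding genes in wild type and 1132 in the knockout-labelled library, and 927 genes had them in both. At limits of 5 and 4, 4039 and 1190 peaks were left. The limits asked more of the shallower input: with 1 input read, a cluster needed 5 IP reads to pass in wild type and 9 in the knockout-labelled library. With the wild-type input thinned to the depth ratio of the other pair, a setting chosen after seeing the data, a mean of 2973.1 wild-type peaks passed (2950 to 2997 over 20 draws).

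Enriched AGO2 peaks of wild type lay mostly in introns, 3' UTRs and coding sequence. Those of the knockout-labelled library lay mostly in 3' UTRs, exons of non-coding genes and coding sequence. Of wild-type enriched peaks, 28.2% were in 3' UTRs (27.3 to 29.0), 26.0% in coding sequence (25.2 to 26.8), 35.2% in introns (34.3 to 36.1) and 4.15% in 5' UTRs (3.79 to 4.53). Of knockout-labelled peaks, 36.1% were in 3' UTRs (34.2 to 37.9), 19.5% in coding sequence (18 to 21.1), 16.5% in introns (15.1 to 18) and 6.04% in 5' UTRs (5.16 to 7.01). Exons of non-coding genes, which include the miRNA genes, held 6.36% of wild-type peaks (5.92 to 6.83) and 21.6% of knockout-labelled peaks (20.1 to 23.2), and intergenic sequence 0.151% and 0.264%. When the same number of peaks was taken from each library, the wild-type shares became 35.6% for 3' UTRs, 20.9% for coding sequence, 17.7% for introns, 4.07% for 5' UTRs and 21.6% for non-coding exons. At limits of 5 for -log10 p and 4 for log2, 3' UTRs held 35.8% of wild-type (34.3 to 37.3) and 32.9% of knockout-labelled peaks (30.3 to 35.7), so the order of the libraries turned. Coding sequence then held 8.49% of knockout-labelled peaks, and non-coding exons 14.7% of wild-type and 41.1% of knockout-labelled peaks.

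**Figure D1:**
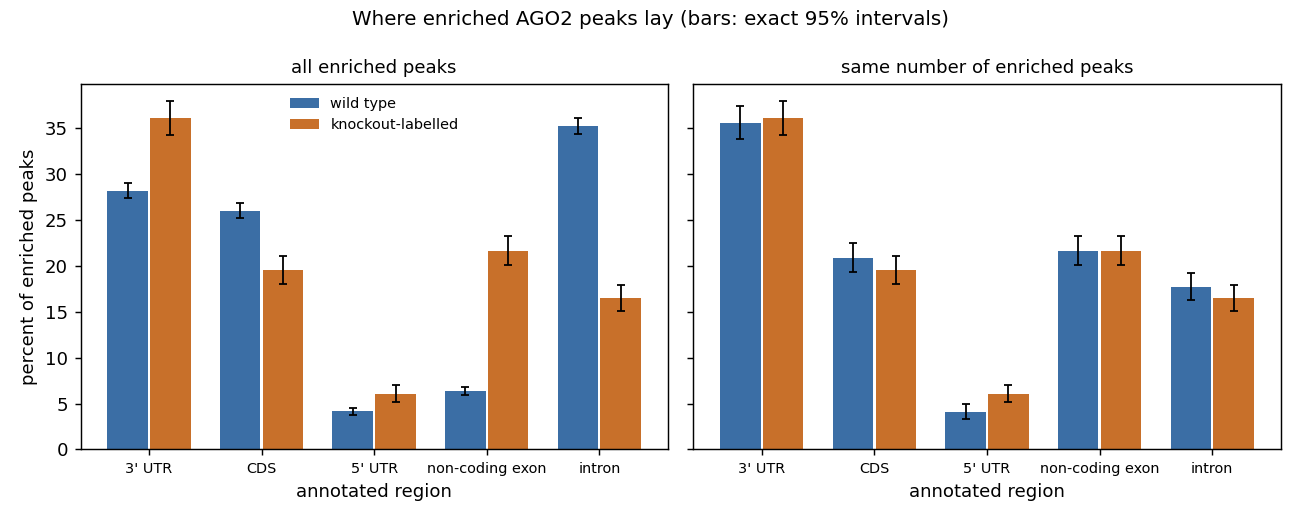
Percent of enriched AGO2 peaks in each annotated region, for all enriched peaks (left panel) and for the same number from each library, ranked by -log10 p (right panel); bars are 1 library each and lines are exact 95% binomial intervals. The 3' UTR share was 28.2% in wild type and 36.1% in the knockout-labelled library with all peaks, and 35.6% and 36.1% with equal numbers.

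The sites of both libraries were compared to ask which AGO2 sites are seen with and without FMRP. Sites at miRNA genes were shared most: 84.2% of wild-type peaks there (81.0 to 87.1) and 96.9% of knockout-labelled peaks (95 to 98.3) overlapped an enriched peak of the other library. Abutting peaks at miRNA genes were counted separately, though they may share reads. In 3' UTRs the shares were 21% (19.6 to 22.5) and 67.9% (64.8 to 70.8), in coding sequence 7.71% (6.77 to 8.73) and 42.1% (37.8 to 46.5), in 5' UTRs 12% (9.17 to 15.3) and 33.1% (25.9 to 41.0), and in introns 5.66% (4.97 to 6.43) and 54.2% (49.4 to 59.0). Over all regions, 1699 wild-type peaks (15.1%, 14.4 to 15.7) and 1674 knockout-labelled peaks (63.1%, 61.3 to 65.0) did so. After the peaks were moved to random places in the same kind of region of the same gene, means of 4.03% and 16.6% overlapped, and the highest of 100 moves gave 4.55% and 18.2%. At limits of 5 and 4 the shares were 25.2% and 83.7%. With equal numbers of peaks, both shares were 49.8%, and against any cluster of the other library they were 39.6% and 73.9%, where moved peaks gave 14.2% and 21.6%. Of clusters with 20 or more IP reads, 98.1% in wild type (97.1 to 98.8) and 81.3% in the knockout-labelled library (79.7 to 82.8) overlapped a cluster of the other library.

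Some well-covered sites had no cluster of the other library within 50 bases. They were ranked by -log10 p after the data had been seen. In wild type they were led by a 3' UTR peak of Enah, an actin regulator gene (chromosome 1, 181904453 to 181904524; 33 IP against 15 input reads, log2 3.80), and included Meg3, an imprinted non-coding RNA (3.05). Further wild-type sites lay in the 3' UTRs of Arf3 (24 against 1 reads, log2 7.25), Sema7a, a semaphorin gene (6.19), the cytokine signalling inhibitor gene Socs1 (7.06), Plec (6.91), Sox12 (5.12), Zbtb7a (4.80) and Vat1 (6.83), and in the coding sequence of Atp1b2 (7.06). In the knockout-labelled library they were led by a coding peak of Map1b, a microtubule-binding protein gene and known FMRP target (chromosome 13, 99432044 to 99432075; 62 against 9 reads, log2 3.72). The others lay on the glutamate receptor gene Grik3 (3' UTR, 3.07), 4930402H24Rik (3' UTR, 5.33), Sept3 (3' UTR, 4.40), the kinesin gene Kif21b (5' UTR, 3.42), the chromatin remodeller gene Smarca4 (coding, 3.42) and Nav1 (coding, 3.58). The snoRNA genes Gm25615 (3.10) and Snord14a (3.18) and the imprinted Peg13 (4.05) also belonged to this set.

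At sites called in both libraries, AGO2 RNA stood further above input in wild type, least clearly in exons of non-coding genes. Over 10804 clusters called in both, enriched or not, wild-type log2 over input exceeded the other by a median of 1.72 (quartiles 0.92 and 2.42), and 91.9% were higher in wild type. A cluster with equal IP reads and equal input reads in both pairs takes exactly this median. For such a cluster it comes from the log2 depth ratios of input over IP, 2.66 in wild type and 0.94 in the knockout-labelled pair. Because input reads of 0 were counted as 1, clusters with few input reads can take it without a difference in enrichment. Over 4465 wild-type enriched peaks on a knockout-labelled cluster, which were chosen for a high wild-type value, the median was 2.11 (1.46 and 2.88). Among these peaks it was 2.06 at miRNA genes, 2.40 in coding sequence, 1.95 in 3' UTRs, 2.21 in 5' UTRs, 2.18 in introns and 1.82 in non-coding exons outside miRNA genes. In 3800 of all clusters called in both, those with at least 5 reads in each input, it was 1.43 (0.74 and 2.11), and 90.7% were higher in wild type, but in those non-coding exons it was 0.28 (-0.40 and 1.01), with 58.8% higher. Each value divides by a different input library, so the inputs enter this difference as well as the IPs. In the authors' deposited table, which sets the IPs directly against each other, regions with 20 or more reads had lower medians. They were 0.08 in coding sequence, 0.60 in introns and 0.77 in 3' UTRs, where clusters with at least 5 reads in each input gave 1.38, 1.78 and 1.43. The sets of regions differ. With no read limit, where most regions rest on few reads, the deposited medians were 1.77 in coding sequence, 2.77 in introns and 1.93 in 3' UTRs. The same clusters were not compared, so how much of the difference the inputs hold is not known.

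The authors' deposited table sets the wild-type IP directly against the knockout-labelled IP. The 10 genes ranked highest in the authors' deposited table were Mir124a-2 (log2 3.02), Snhg11, a host gene of small nucleolar RNAs (2.79), Mir124a-1 (2.58), Mir128-1 (1.95), Mir495 and Mir451a (1.75 each), Mirlet7b (1.70), Mirlet7c-1 (1.62), Mir298 (1.60) and Mir125a (1.56), each at the largest listed -log10 p of 400. Over 236 miRNA genes the median log2 in the authors' deposited table was 1.51 (quartiles 1.22 and 1.88), and 187 were past the limits of 3 for -log10 p and 1 for log2. Here each miRNA gene took its region with the highest -log10 p, among regions with 20 or more reads or a -log10 p of 400. Regions below 0 list a -log10 p of 0, so this choice favours higher regions. The family medians rest on the same choice. By family, the medians in the authors' deposited table were 3.02 for the 3 miR-9 genes, 2.72 for the 3 miR-124 genes, 2.25 for the 3 miR-125 genes, 2.20 for the 2 miR-128 genes, 1.49 for the 6 miR-30 genes, 1.49 for 9 genes of the miR-17 to 92 clusters and 1.45 for the 9 let-7 genes. The miRNA genes as a whole and these families were above 0 as deposited and above 0.38, the median of 3124 regions with 20 or more reads outside miRNA genes. Against the median of all regions, 2.77, miR-9 stayed above, and the miRNA genes as a whole and the other families turned to below. That median is the value of 3 wild-type reads against at most 1 knockout-labelled read. It therefore sets regions with unlike numbers of reads against each other.

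Protein-coding genes were ranked in the same way after the data had been seen. Igf2 (5' UTR, 773 wild-type against 771 knockout-labelled reads) had a log2 of 1.19 in the authors' deposited table. Kdm6b (coding, 311 against 335 reads) had 1.08, Kcnk10 (3' UTR, 191 against 176) 1.31 and Tnrc6a, which encodes a scaffold of the silencing complex (coding, 185 against 169), 1.32 in the authors' deposited table. Next in the authors' deposited table were Klf13 (3' UTR, 103 against 64 reads, 1.87), Rpl14 (coding, 136 against 112, 1.47), Pcdh1 (3' UTR, 220 against 242, 1.05) and Cmip (coding, 94 against 70, 1.61). These 8 genes lay above 0.38 and below 2.77, the median of all regions.

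Small nucleolar RNAs went the other way. The authors' deposited table lists a -log10 p of 0 for all 2915 regions with log2 below 0, so no region could pass as lower by the deposited scores. With p computed from the recovered reads in both directions, a setting chosen after seeing the data, 82 regions were past the limits as lower in wild type, of which 39 lay in 29 snoRNA and scaRNA genes, 3 in snRNA genes and 32 in protein-coding genes. The lowest by that p were Snord13 (log2 -2.15 in the authors' deposited table), Snord83b (-2.61, 57 wild-type against 794 knockout-labelled reads), 2410002F23Rik (5' UTR, -2.39, 37 against 443), Gm26917 (-1.57) and Snord32a (-1.61). Scarna2 (-2.48), Snord118 (-1.11), Snord47 (-2.41), Snord14d (-2.87) and Snord14c (-2.30) followed in the authors' deposited table. Over 77 snoRNA and scaRNA regions with 20 or more reads, the median log2 in the authors' deposited table was -1.48 (quartiles -2.20 and -0.70), and 63 were below 0. Exonic lower regions lay on 14 protein-coding genes, and in the authors' deposited table these included the presynaptic scaffold genes Pclo (coding, -2.34, 16 against 184 reads) and Erc2 (5' UTR, -2.84), Map1b (coding, -1.20, 56 against 293), Ttc3 (-2.02), Hist1h1d (-2.15), Basp1 (-1.65), Mapt, the tau gene (5' UTR, -2.07), Sptbn1 (-2.55) and Apc (-1.32). Further ones were Kif1a (-2.16), Son (-1.60) and Prrc2c (-1.86) in the authors' deposited table, and the protein-coding genes were ranked after the data had been seen.

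In all, 1590 regions of the authors' deposited table were past the limits as higher in wild type and 0 as lower. At limits of 5 and 2, 184 were higher. With p in both directions the counts were 1554 and 82. Centred on the median of all regions, which shifts every log2 by 2.77, they were 636 and 473, but all 473 had a deposited log2 above 0 and passed the p limit as higher, so no p stands behind the word lower there. With p in both directions and centring on 0.38 the counts were 752 and 151. The regions were chosen in the wild-type IP, and 13257 of them rest on 3 wild-type reads against at most 1 knockout-labelled read. Outside miRNA genes, the median log2 in the authors' deposited table was 2.77 in 21791 regions with 4 to 5 reads, 0.43 in 2162 regions with 21 to 50 and 0.12 in 101 regions with over 200. At miRNA genes it was 1.56 in 78 regions with 21 to 50 reads, 1.5 in 239 with 51 to 200 and 1.44 in 172 with over 200 (quartiles 1.24 and 1.61). Abutting regions that may share reads were counted separately there. Among regions with 20 or more reads, the medians in the authors' deposited table were 0.77 in 3' UTRs (914 regions), 0.60 in introns (520), 0.08 in coding sequence (1322), 0.02 in 5' UTRs (190) and -0.34 in non-coding exons outside miRNA genes (172), against 1.48 at miRNA genes (491).

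**Figure D2:**
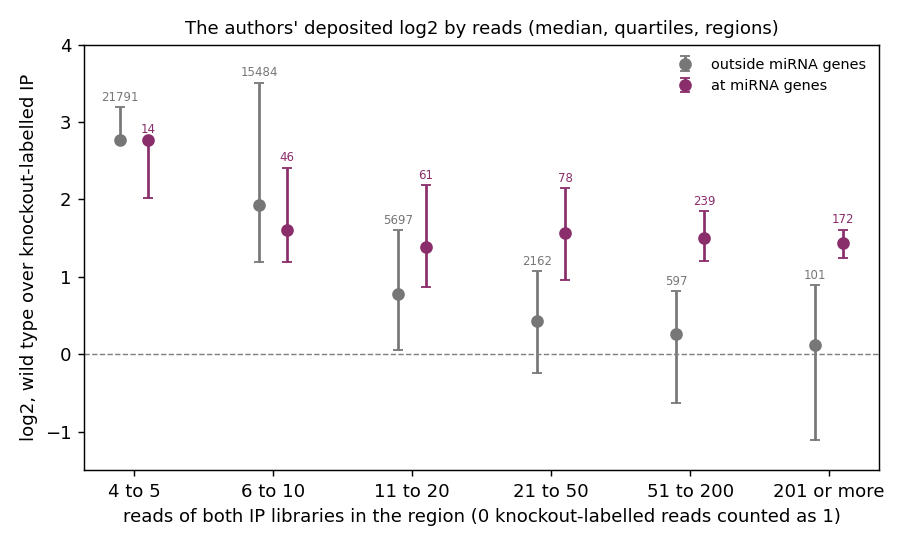
Median and quartiles of the authors' deposited log2 of the wild-type over the knockout-labelled IP, by the reads of both IP libraries in the region, for regions at miRNA genes and elsewhere; the small numbers count regions. Outside miRNA genes the median went from 2.77 at 4 to 5 reads to 0.12 above 200 reads, while at miRNA genes above 200 reads it was 1.44, above 0 but below the median of all regions, 2.77. The median of all regions is the value of 3 wild-type reads against at most 1 knockout-labelled read.

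FMRP-bound mRNAs had regions on both sides. Of 40 genes on this list, 7 had an exonic region past the limits as higher in wild type in the authors' deposited table. By the added p from recovered reads, which is meant by lower here and for the lists below, 4 of the 40 had one past the limits as lower. Over all protein-coding genes with a region in that table, 525 of 6536 had one past the limits as higher. The counts of this list and those below are to be read beside that share, and genes with many clusters have more chances to pass. The higher ones were led in the authors' deposited table by the postsynaptic scaffold gene Shank3 (3' UTR, log2 4.65, 11 against 1 reads), Adcy1 (3' UTR, 4.36), the presynaptic scaffold gene Bsn (coding, 3.65) and Huwe1 (5' UTR, 2.93). Members of all lists were named by the largest log2, which picks regions with few reads. In the lists, 4.65, 4.51 and 4.36 stand for 11, 10 and 9 wild-type reads against at most 1 knockout-labelled read. A value of 4.19 stands for 8 against at most 1, or for 16 against 2 in Acvr1b. The lower ones were Pclo (-2.34), Kif1a, a kinesin gene (-2.16), Map1b (-1.69 at a region of 24 against 176 reads) and Apc (-1.32) in the authors' deposited table, each in coding sequence. Low p needs reads, so 24 of these genes with a region of 20 or more reads were set against random lists matched in bins on the reads of the best-covered region, a test added after the data had been seen. Those lists held a mean of 0.689 genes with a lower region, and 0.27% held 4 or more. The median gene value of the list was 1.40 against 1.26 in random lists (percentile 69.4 of 10000), but against lists matched on exonic length it lay below their central 95% (percentile 0.33), and against lists matched on median reads per region it was inside (percentile 45.4). Percentiles among random lists describe these libraries only, since genes are not replicates.

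Of 26 genes of the miRNA pathway, 4 had a region past the limits as higher in wild type and 0 a lower one. In the authors' deposited table they were Ago1 (5' UTR, log2 4.51, 10 against 1 reads), Ago2 (3' UTR, 4.36), Tnrc6c (coding, 3.36) and Tnrc6a (coding, 2.93 at a region of 10 against 3 reads). The median of the list was 2.11 against 1.77 in random lists (percentile 92.1). Of let-7 targets 4 of 24 were higher in the authors' deposited table, the activin receptor gene Acvr1b (3' UTR, 4.19), Map4k3 (coding, 4.19), E2f5 (coding, 3.65) and Nras (3' UTR, 1.85), with a list median of 2.02 against 1.81 (percentile 71.8). Of miR-124 targets 4 of 25 were higher in the authors' deposited table, Lamc1 (4.51), Cd164 (4.19), Sp1 (2.02) and the splicing repressor gene Ptbp1 (1.23), all in 3' UTRs, with a median of 1.77 against 2.06 (percentile 18.7). Of miR-9 targets 5 of 21 were higher, led in the authors' deposited table by Sirt1 (4.36), Rap2a (3.77) and Foxp2 (3.09) in 3' UTRs and Stmn1 (coding, 1.77), and Map1b was lower. The median of this list was 2.64 against 1.90 (percentile 95.3). No target list lay outside the central 95% of its random lists.

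Translation, neuron and cytoskeleton genes had the lowest list medians. Of 30 translation and ribosome genes, only 17 had a region in the authors' deposited table, and none of these was past the limits. The median in the authors' deposited table was 0.67 against 2.19 in random lists (percentile 0). Eif4g2 (gene value 0.19, with 6 enriched wild-type and 1 knockout-labelled peaks), Rpl32 (0.67), Pabpc1 (1.07) and Eef1b2 (-1.78) had the most enriched peaks. Among cytoskeleton and axon guidance genes 10 of 36 were higher, led in the authors' deposited table by the guidance receptor genes Robo1 (coding, 4.51) and Plxna1 (coding, 4.19), Dcx (5' UTR, 3.41) and Dpysl2 (5' UTR, 2.69), and Mapt was lower. This list's median was 0.86 against 1.47 (percentile 0.01), and it was inside the central 95% when each gene took the value of its region with the highest -log10 p (percentile 17.4). Of neuron markers 2 of 10 were higher in the authors' deposited table, Dcx (3.41) and Map2 (coding, 1.54), and the median was 0.51 against 1.48 (percentile 0.06). Tubb3, Map2, Stmn2, Gap43 and Dcx stand on both of these lists. With 3' UTR regions alone, the translation list kept 3 genes and was inside (percentile 5.77). Log2 falls with reads, so lists were also matched on median reads per region, a setting added after the data had been seen. The cytoskeleton list then stayed below (median of random lists 1.36, percentile 0.21), but the neuron list was inside the central 95% (1.09, percentile 3.66) and the translation list lay on its lower bound (1.19, percentile 2.44), so part of their low medians goes with coverage.

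Of 32 transcription factors of neuron formation, 8 had a region higher in wild type, led in the authors' deposited table by Mef2c (3' UTR, 4.65), Sox4 (3' UTR, 4.36), Nfib (coding, 3.77) and Foxp2 (3.09). Of 39 synapse and ion channel genes, 4 did in the authors' deposited table: the vesicular GABA transporter gene Slc32a1 (3' UTR, 4.36), Syt4 (coding, 4.19), Dlgap1 (coding, 3.89) and Syn1 (coding, 2.77). In that order they rest on 9 against 1, 8 against 1, 13 against 2 and 12 against 4 reads. The list medians were 1.25 against 1.69 (percentile 8.89) and 1.32 against 1.68 (percentile 8.66), and matched on exonic length both lay below the random lists (percentiles 0.445 and 0.165). With each gene's region of highest -log10 p, both turned to the upper side, inside the central 95% (percentiles 73.3 and 76.4). With 3' UTR regions alone, the synapse list lay below (percentile 0.26) and the transcription factors inside (percentile 2.56). Matched on median reads per region, the synapse list lay below (percentile 1.16) and the transcription factors inside (percentile 21.8). Of 24 cell cycle genes, 15 had a region in that table and 1 was higher, E2f5, with a list median of 1.98 against 2.19 (percentile 39.4).

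Markers of other brain cell types had few regions. Neural progenitor and radial glia markers had 0 of 10 past the limits and a median of 1.82 against 1.86 (percentile 48.3), and Mki67, a proliferation marker, had the most enriched peaks, 2 in wild type and 1 in the knockout-labelled library, ahead of Vim and Hes5. Of 8 astrocyte markers, the water channel gene Aqp4 (3' UTR, log2 3.06 in the authors' deposited table) was higher, and the median was 1.58 against 2.16 (percentile 14.8). No microglia or endothelial and mural marker was past the limits; 3 microglia markers with a value had a median of 3.19 against 2.77 (percentile 89.0), with Csf1r the most enriched, and 4 endothelial and mural markers had 2.77 against 2.48 (percentile 73.7), with Vtn the most enriched. Oligodendrocyte lineage, erythroid and choroid plexus markers had values for 2 genes each, too few for a median. In the authors' deposited table the haemoglobin gene Hbb-bs (coding, 1.70, 27 against 19 reads) and the choroid plexus gene Ttr (coding, 1.60, 28 against 21) were past the limits, while Olig1 had a gene value of 2.32 and was not.

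Seed matches of brain miRNAs marked the 3' UTR peaks of both libraries. Sites for 24 families expressed in brain (7mer-m8) lay in 33.0% of 3173 wild-type peaks against 10.1% of same-length windows of the same 3' UTRs outside clusters, a ratio of 3.26 (3.03 to 3.49 over resampled genes), and in 52.3% of 946 knockout-labelled peaks against 14.3% of windows, a ratio of 3.65 (3.28 to 4.10). The neuronal miR-124 (ratio 21.8, 16.3 to 31.4, in wild type; 29.6, 17.7 to 63.2, in the knockout-labelled library) and let-7 (19.8, 13.2 to 32.5; 38.9, 19.3 to 123.3) stood highest. With peaks extended by 25 bases they stayed highest but fell to 12.4 (9.54 to 16.4) and 18.7 (13.1 to 30) for miR-124 and 9.28 (6.65 to 13.2) and 14.5 (9.05 to 25.7) for let-7. With peaks as called, they were followed in wild type by miR-9 (5.57 and 4.33), the miR-17 family (5.51 and 6.25), the miR-130 family (5.09 and 5.37), miR-19 (4.92 and 4.44), miR-125 (4.83 and 3.47), miR-30 (4.74 and 8.86) and miR-153 (4.61 and 3.26). The knockout-labelled order differed, with miR-30 highest among these. Ratios for miR-218 (1.15 and 0.909), miR-23 (1.08 and 1.18), miR-34 (1.0 and 1.17), miR-138 (0.978 and 1.78), miR-29 (1.59 and 0.938) and miR-101 (1.32 and 2.20) had intervals that held 1 in both libraries, and those of miR-137, miR-27 and miR-103 held 1 in the knockout-labelled library. The miR-132 family lay below 1 in wild type (0.50, 0.156 to 0.956; 0.652, 0 to 1.76, in the knockout-labelled library). Families of other tissues together gave 0.744 (0.485 to 1.1) and 1.1 (0.574 to 1.83). Of these, miR-208 had sites in 6 wild-type peaks, a ratio of 6.0 with no interval (4.09, 1.25 to 11.7, with peaks extended by 25 bases), and in 0 knockout-labelled peaks. The ratio for brain families moved to 5.12 and 8.73 against 3' UTR clusters at or below input, which numbered only 31 in wild type and 200 in the knockout-labelled library and gave no interval, to 2.17 in wild type with peaks extended by 25 bases, and to 6.58 in the knockout-labelled library for 8mer sites.

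**Figure D3:**
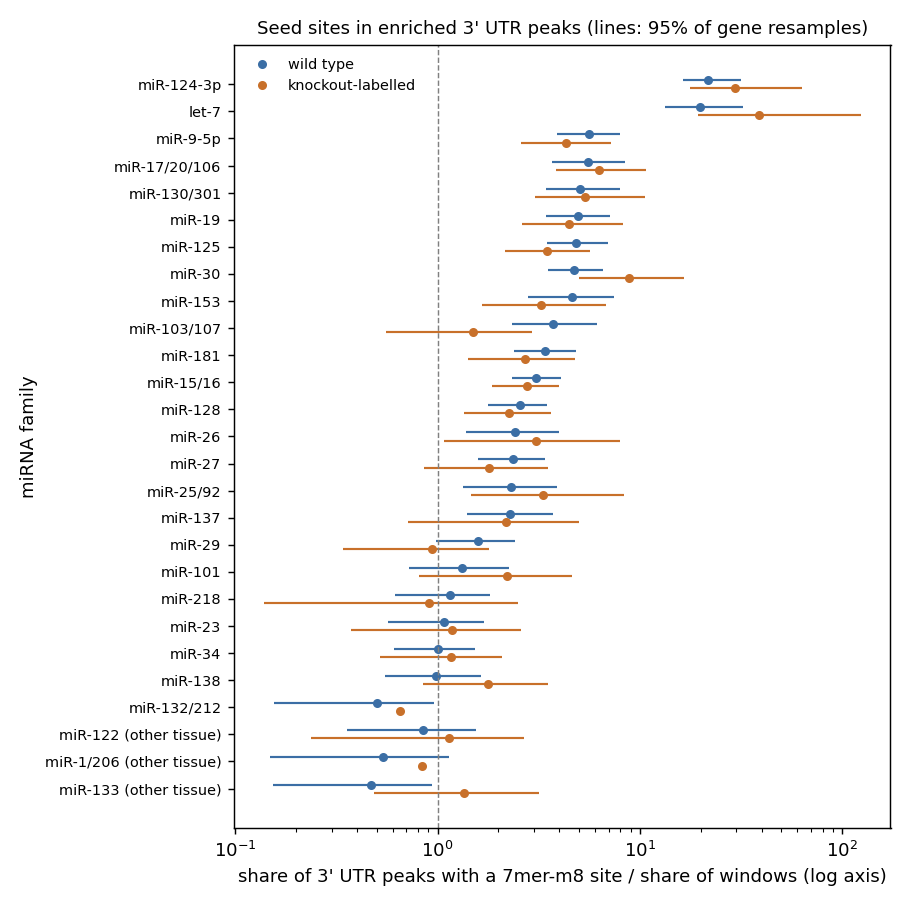
Share of enriched 3' UTR peaks with a seed site divided by the share of windows from the same 3' UTRs, on a log axis, for each miRNA family and library; lines span 95% of 1000 gene resamples, points without a line have no interval above 0, and miR-208 is not drawn because its sites were too few. The highest ratios were those of miR-124 (21.8 and 29.6) and let-7 (19.8 and 38.9), which fell to 12.4 and 18.7, and to 9.28 and 14.5, with peaks extended by 25 bases, and miR-34 lay at 1.0 in wild type.

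Examples were taken from the best-scoring peaks that were enriched in both libraries, after their values were seen. The miR-124 site GTGCCTT lay at 3298142 to 3298148 in the Myadm 3' UTR peak (chromosome 7, 3298094 to 3298192; log2 over input 8.68 in wild type and 6.44 in the knockout-labelled library) and in that of Pcdh1 (chromosome 18, 38189639 to 38189713; 6.48 and 4.92). The let-7 site CTACCTC lay in 3' UTR peaks of Runx1t1 (chromosome 4, 13892679 to 13892798; 5.96 and 4.80) and Igdcc4 (chromosome 9, 65136277 to 65136376; 6.47 and 6.58). A miR-9 site lay in the 3' UTR of Map1b (chromosome 13, 99424871 to 99424910; 4.52 and 4.46) and of Pou2f1 (7.83 and 4.48), a miR-17 site in Tbc1d9 (7.36 and 6.67) and a miR-30 site in Sbf1 (8.39 and 6.60). In the authors' deposited table, 442 regions of 3' UTRs with 20 or more reads and a brain seed site within 25 bases had a median log2 of 0.85 (quartiles 0.28 and 1.32), and 472 without had 0.68 (0.11 and 1.25). By family, the medians in the authors' deposited table were 1.19 for miR-15/16, 1.07 for miR-128, 0.87 for let-7, 0.69 for miR-124 and 0.34 for miR-138.

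The series title names G-quadruplexes, structures of stacked guanines, and predicted ones were sought within 50 bases of enriched exonic peaks. They were found near peaks of let-7b (Mirlet7b), Mir484 and Mir149, and of the 3' UTRs of Klf13 (log2 over input 7.77; GGGTTGGGGGGGAGGGGGAGGG), Pou2f1 (7.83), Sema7a (8.73), Iglon5 (5.16) and Nfix (5.10), genes chosen after their values were seen. Near 5' UTR peaks the share was 13.9% in wild type (10.9 to 17.4) and 13.8% in the knockout-labelled library (8.82 to 20.1), against 9.96% and 11.8% of windows in the same kind of region of the same genes. It was 4.24% (3.57 to 5.0) and 5.33% (4.0 to 6.95) near 3' UTR peaks, against 2.51% and 2.97% of windows, and 1.53% (1.12 to 2.05) and 3.86% (2.37 to 5.90) near coding peaks, against 1.2% and 2.12%.

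Knockout-labelled peaks that lay on no wild-type cluster had a predicted G-quadruplex in 42 of 548 cases (7.66%, 5.58 to 10.2), against a mean of 4.14% of matched windows and a highest draw of 5.29%. At limits of 5 and 4 the excess was not clear: 5 of 65 such peaks had a motif (7.69%, 2.54 to 17), no more than the highest draw of windows. Of 226 knockout-labelled peaks on a wild-type cluster that was not enriched, 1.33% had one (0.275 to 3.83, windows 2.04%). Of 2319 wild-type peaks on a knockout-labelled cluster that was not enriched, 4.10% had one (3.33 to 4.98), against 2.55% of windows and a highest draw of 2.85%. The share was 3.02% (2.48 to 3.64; windows 2.07%) for wild-type peaks on no knockout-labelled cluster, and 3.74% (2.83 to 4.85; windows 2.83%) and 4.05% (3.09 to 5.20; windows 3.04%) for the wild-type and knockout-labelled peaks seen in both. With the looser motif of 2 guanines per run, the shares were 48.2% near knockout-labelled peaks on no wild-type cluster (windows 39.3%) and 29.9% near wild-type peaks on no knockout-labelled cluster (windows 28%). Without extension they were 3.10% and 0.911% (windows 1.59% and 0.364%). With equal numbers of peaks, 394 wild-type peaks on no knockout-labelled cluster were left, and 5.08% had a motif (3.13 to 7.73; windows 3.53%), an interval that overlaps that of the knockout-labelled peaks. In 3' UTRs, the share was 3.36% (2.48 to 4.44) near wild-type peaks with a brain seed site within 25 bases and 4.94% (3.98 to 6.05) near those without, and 4.61% (3.06 to 6.63) and 6.49% (4.2 to 9.5) in the knockout-labelled library. In the authors' deposited table, 62 regions of 3' UTRs with 20 or more reads and a motif had a median log2 of 0.90 (quartiles 0.30 and 1.24), and 852 without had 0.75 (0.19 and 1.29). Medians in the authors' deposited table were -0.02 with a motif and 0.08 without in coding sequence, and 0.19 and -0.03 in 5' UTRs.

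**Figure D4:**
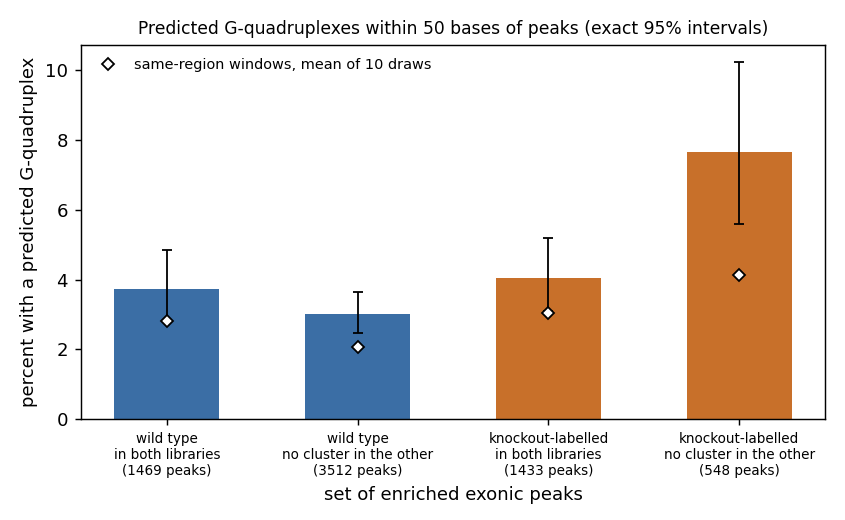
Percent of enriched exonic peaks with a predicted G-quadruplex within 50 bases, for peaks seen in both libraries and for peaks on no cluster of the other library; lines are exact 95% binomial intervals and diamonds are the mean of 10 draws of same-length windows from the same kind of region of the same genes. Knockout-labelled peaks on no wild-type cluster stood at 7.66% against 4.14% of windows.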

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

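Tests chosen only after the results were seen were the thinned input, merged peaks, peaks at miRNA genes left out, p in both directions, reads summed per gene, lists matched on reads and peaks extended by 25 bases. Under alternatives, 90 values stayed within the interval of the reported value, 1.5 times its count or 1 SD of the random lists, and 92 moved. No list that lay outside the random lists changed its direction, but 13 of 74 list differences took another sign, all of lists within the central 95% of random lists as reported, among them FMRP-bound mRNAs, transcription factors, synapse, cell cycle and progenitor genes. The cause was not tested except where the setting itself gives it, as with fewer peaks under stricter limits.

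At a -log10 p of 5 and log2 of 4, enriched peaks numbered 4039 in wild type and 1190 in the knockout-labelled library, the 3' UTR shares were 35.8% and 32.9%, in the opposite order to those reported, the overlaps 25.2% and 83.7%, the wild-type seed ratio 3.77 and the motif share of wild-type peaks on no knockout-labelled cluster 4.16%. At a log2 of 1, the knockout-labelled 3' UTR share was 28.9%, the overlaps were 18.4% and 56.7%, and the knockout-labelled seed ratio was 3.28. With equal numbers of peaks, the wild-type 3' UTR share was 35.6%, both overlaps were 49.8% and the motif share of wild-type peaks on no knockout-labelled cluster was 5.08%. With the wild-type input thinned, 2973.1 wild-type peaks passed.

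With peaks at miRNA genes left out, the 3' UTR shares were 29.6% and 43.9% and the overlaps 11.3% and 55.5%. With bases counted, the 3' UTR shares were 31.7% and 43.4%. The overlaps were 11.8% and 50.4% at a reciprocal overlap of 50%, 16.2% and 65.4% within 50 bases, 39.6% and 73.9% against any cluster, and 14.1% and 58.5% with abutting peaks merged. Other shares of coding sequence and introns stayed within their interval in 8 of 24 cases.

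In the series table, 184 regions were higher at a -log10 p of 5 and log2 of 2. Centred on the median of all regions, 636 were higher and 473 lower, though those 473 passed the p limit as higher. With p in both directions 82 were lower; and with p in both directions, centred on well-covered regions outside miRNA genes, 752 were higher and 151 lower. Matched on exonic length, 6 lists lay outside the central 95% of random lists instead of 3, and matched on median reads per region 2 did, without the translation and neuron lists. Over all alternatives, 50 of 74 list differences stayed within 1 SD.

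Seed ratios were 4.75 and 6.58 for 8mer sites, 5.12 and 8.73 against 3' UTR clusters at or below input, and 2.17 and 2.52 with peaks extended by 25 bases, where miR-124 fell to 12.4 and 18.7 and let-7 to 9.28 and 14.5. Motif shares, in the order wild type in both, wild type alone, knockout-labelled in both and knockout-labelled alone, were 27.0%, 29.9%, 28.9% and 48.2% with 2 guanines per run, and 1.5%, 0.911%, 1.47% and 3.10% without extension. Depth limits the sites with few reads most: 46.4% of wild-type and 46.1% of knockout-labelled clusters with recovered reads rest on 3 IP reads.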

Other observations

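Of the tests below, the one with the wild-type input thinned and the one on regions of miRNA genes with many reads were chosen only after the result was seen, as were the groups of miRNA genes in the next paragraph.

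Beyond the families described, the miRNA genes far above in the wild-type IP included the miR-200 family, known from epithelia, the miR-182 to 96 cluster, known from sensory cells, and miR-375, known from endocrine cells. Each miRNA gene again took its region with the highest -log10 p, a choice that favours higher regions. Mir200c (log2 4.80, 61 wild-type against 5 knockout-labelled reads), Mir200a (3.96, 109 against 16), Mir141 (3.87, 96 against 15), Mir96 (3.74, 47 against 8), Mir200b (3.52), Mir375 (3.32, 70 against 16), Mir429 (3.09, 157 against 42) and Mir182 (2.98, 159 against 46) had a median of 3.63 in the authors' deposited table. They made up 7 of the 10 highest of 236 miRNA genes in the authors' deposited table, where Mir26a-2 (3.14, 85 against 22) also stood, and each also lay above the median of all regions, 2.77. Below 0 in the authors' deposited table were 6 miRNA genes: Mir10a (-0.44, 12 against 37) and Mir10b (-1.06, 4 against 19), which sit in the Hox clusters, and Gm24270 (-0.46), Mir501 (-0.46), Mir1291 (-1.40) and mmu-mir-3535 (-1.86). With 1 library per genotype, a difference between brains or their preparation is not separated from one between genotypes.

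The wild-type library had 4.26 times as many enriched peaks as the knockout-labelled library. A candidate explanation is that its input was deep relative to its IP, so that fewer IP reads sufficed. With the input reads thinned to the depth ratio of the other pair, the ratio was 1.12. Most of the difference in number thus went away when this depth ratio was matched. The thinning left the IPs at unequal depth, the knockout-labelled one 2.28 times as deep, so the numbers at equal depth are not known. The number of enriched peaks therefore gives no measure of AGO2 binding with and without FMRP, and a biological part stays open.

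At sites called in both libraries, the knockout-labelled library was less enriched over input by a median of 1.72 over all clusters called in both. Equal IP reads and equal input reads in both pairs give exactly this value, from the log2 depth ratios of 2.66 and 0.94. Scores are scaled to depth, so with many reads such counts would be a difference in enrichment. With input reads of 0 or 1 they need not be, so by itself the value does not measure lost enrichment. Input reads of 0 that were counted as 1 could raise such a difference where depths are unequal. Among these clusters, with 5 or more reads in both inputs, the median difference was still 1.43 (quartiles 0.74 and 2.11), though 0.28 in non-coding exons outside miRNA genes. This argues against such counting as the whole cause over the sites with that many input reads. Clusters at miRNA genes were not taken apart there. Set directly against each other, the IPs differed less in regions with 20 or more reads. The medians in the authors' deposited table were 0.08 in coding sequence and 0.60 in introns. With no read limit they were 1.77 and 2.77, and the same clusters were not compared. How much of the difference the inputs hold is therefore not known. A weaker immunoprecipitation, a different input and an effect of the genotype stay open, since each genotype has 1 library.

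Regions at miRNA genes were higher in the wild-type IP. Their median lay below that of all regions, 2.77, the value of 3 wild-type reads against at most 1 knockout-labelled read. The choice of regions in the wild-type library, many with few reads, might give the higher values. In regions with over 200 reads, however, the median log2 in the authors' deposited table was 1.44 at miRNA genes and 0.12 elsewhere. The tables therefore argue against that choice as the whole cause. A larger share of RNA not held by AGO2 in the knockout-labelled IP may also lower every AGO2-bound RNA there. Outside miRNA genes, regions on knockout-labelled enriched peaks had a median 0.459 above regions on its clusters near input (0.322 to 0.541 over resampled genes, an interval added after the value was seen). Both ends of that interval are positive, so a difference was seen. The size asked for beforehand, 0.5, lies within the interval, so the test does not decide on this explanation. The snoRNA regions had a median of -1.48 in the authors' deposited table, but whether their RNA was held by AGO2 was not tested. The snoRNA genes Gm25615 and Snord14a had peaks above input in the knockout-labelled library (log2 3.10 and 3.18), but they were picked from enriched peaks. In non-coding exons outside miRNA genes, clusters called in both libraries with 5 or more reads in each input had a knockout-labelled median of 0.13. An effect of the genotype on miRNAs held by AGO2 is also untested.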
